A study of Mus musculus with 6 samples.

How the data were processed

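Total RNA of 6 samples of Pmel-1 CD8+ T cells was labelled with biotin and hybridised to Affymetrix arrays, 1 array per sample, per the labels' protocols. The authors deposited 1 table of log2 values for 35556 probe sets, made with RMA per the submitters' processing notes; RMA corrects background, normalises arrays to each other by quantiles and summarises the probes of a probe set. Its version and settings and a genome build were not given in the sources used here. Values ran from 2.51 to 14.72, and the sorted values of single arrays differed from their mean by up to 0.233, so the arrays were close to a common distribution. RMA aligns distributions and would hide a change shared by most genes. Every value column belonged to a sample (0 others).

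Probe sets were named through the platform annotation given with the data, which can be old. Of the probe sets, 21789 carried 1 gene symbol, 1621 several and 12146 were not listed and stayed unnamed. Of the first, 21698 had a gene identifier found in the gene table of assembly GRCm38.p6, which was used for names only; no coordinates are given because no build was named. Each of 19938 genes was represented by its probe set with the highest mean over the 6 arrays. A gene was tested where at least 2 of 6 arrays lay above the 50th percentile of all values (6.83), which left 11147 genes, of which 794 had more than 1 probe set.

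The groups came from the labels. All 6 arrays were fitted together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 mean per group, no replicate block), with 3 residual and 5.62 prior degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method over the tested genes of a comparison with a threshold of 0.05. Tests were two-sided. Of 30 gene lists fixed before the data were examined, 29 were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry; the other held genes that check the sex of the animals, and was checked against the labels. The lists were cytotoxic effector molecules, effector cytokines and chemokines, the type 2 cytokine programme, cytokine receptors, homing and adhesion receptors, naive and memory-associated genes, terminal effector-associated genes, inhibitory receptors, costimulatory receptors, transcription regulators, genes responsive to IL-12 and STAT4 or to IL-2 and STAT5, interferon-stimulated genes, DNA replication, mitosis, glycolysis, oxidative phosphorylation, cholesterol synthesis, amino acid and integrated stress response, pro-apoptotic and anti-apoptotic genes, immediate early genes, CD8 T cell identity, and markers of natural killer, CD4 and regulatory T, B, myeloid and dendritic, MHC class II presenting, and erythroid and platelet cells. The estimated correlation rests on the 3 residual degrees of freedom, so a list not called with it may still have shifted. Counts "adjusted over the list alone" use the same limma p-values adjusted within the list.

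The genes named were, by a rule fixed before the data were examined, the 12 largest rises and 12 largest falls between IL-12 and IL-2 cells and the 8 of each against naive cells, among genes that passed the test with both arrays of one group outside both of the other, leaving out predicted genes and clone names, plus a fixed set of 16 genes and up to 4 members with the smallest adjusted p of each list. Slc16a3, Aldoc, Fosb, Dusp1 and Jun were named after their values were seen.

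The fit was tested on simulated data with 200 of 11147 genes changed, over 20 simulations per comparison. For IL-12 against IL-2, with gene variances drawn from the fitted prior, 95.4% of changes of 1, 99.9% of changes of 2 and 23.6% of changes of 0.5 on the log2 scale were recovered, and 4.54% of calls were false. With each gene's shrunken variance taken as true, which departs from the variance model, 6.42% of calls were false. A list shifted by 0.5 was called by camera with an adjusted p of 5.01e-32, and 0 of 28 other lists were called. The simulated genes varied independently, so this cannot show how often camera calls unshifted lists whose genes vary together.

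Alternatives tried were no filter, a filter at the 75th percentile, the mean or the most variable of a gene's probe sets, quantile normalization, median centring, eBayes with trend and robust estimation, array weights, fits on the compared groups alone, a replicate block, a test against a 1.5-fold change, and leaving out each array. A separate naive array for each primed group was added after seeing the data. Probe sets with several symbols or none were left out of the tests.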

Results

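Gene expression was measured on Affymetrix arrays in CD8+ T cells from the spleens of female C57BL/6 Pmel-1 mice, whose transgenic T cell receptor recognises the melanoma antigen gp100. The 6 arrays fell into 3 groups of 2. Naive cells were taken fresh and sorted as CD8+ Thy1.1+. The other groups were primed with gp100 for 4 days and cultured with IL-2 or with IL-12 for 6 days. The stated purpose was to find genes and pathways needed for activity against tumours by setting IL-12 priming against IL-2 priming. Across 11147 tested genes, the 2 arrays of a group correlated at 0.986 for naive, 0.994 for IL-2 and 0.992 for IL-12 cells, a correlation across genes, which are not independent replicates. The first principal component held 81.2% of the variance and the second 13.5%. Values are log2 RMA values, fold changes are given with the standard error of the limma fit, and adjusted p-values are Benjamini-Hochberg values from that fit. The number of arrays limits the precision, and because no label says that arrays of a group came from separate mice or cultures, the p-values may measure technical spread only.

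In IL-12 primed cells compared with IL-2 primed cells, the largest measured rise was that of Il10 (probe set 10349603), which encodes the cytokine interleukin 10. Its mean log2 value was 10.46 against 5.32, a log2 fold change of 5.14 ± 0.12 (SE, n = 2 arrays per group; limma adjusted p = 3.5e-07). The largest fall was that of Dapl1 (probe set 10472235), from 11.85 in IL-2 to 6.47 in IL-12 cells, a 41.7-fold difference (limma adjusted p = 1.35e-06). Itgae (probe set 10378286), the integrin alpha E chain CD103, was 34.1-fold lower in IL-12 cells (limma adjusted p = 6.01e-07). Ifng, which encodes interferon gamma, was 5.18-fold higher in IL-12 cells. P2rx3, an ATP-gated ion channel, was 24.5-fold higher and Usp18, an interferon-induced ISG15 protease, was 17.3-fold higher. The other largest rises were those of Esm1, Trat1, Prnp, Atp6v0d2, Gadd45g, Gzmk, Gpx8, Cysltr2 and Furin, from 13.1-fold for Esm1 down to 6.85-fold for the proprotein convertase gene Furin. The granzyme gene Gzmk was 7.38-fold higher. Usp18 read 10.84 and 10.03 on the IL-12 arrays and 10.53 and 10.90 on the naive arrays. Trat1 read 8.82 and 9.09 on the IL-12 arrays and 8.70 and 8.96 on the naive arrays. In both genes the IL-2 arrays alone read low. Among the largest falls, the amino acid transporter gene Slc6a19 was 15.2-fold lower and Nrn1 was 11.4-fold lower. Slc28a2b, Pcsk1, Igfbp7, Il6ra, Inpp4b, Eya2, St6gal1 and Mxd4 were 10.4-fold to 4.73-fold lower, and Il6ra, the IL-6 receptor alpha chain, was 5.90-fold lower. Atp6v0d2 read 8.35 and 7.10 on the 2 IL-12 arrays and had a mean of 4.55 in IL-2 cells, a level of Y-linked genes in these female cells, whose group means reached 4.96. Its 9-fold rise was therefore a lower bound, and its rank among the rises is not certain. Each of these 24 genes had both arrays of one group outside both arrays of the other.

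**Figure D1:**
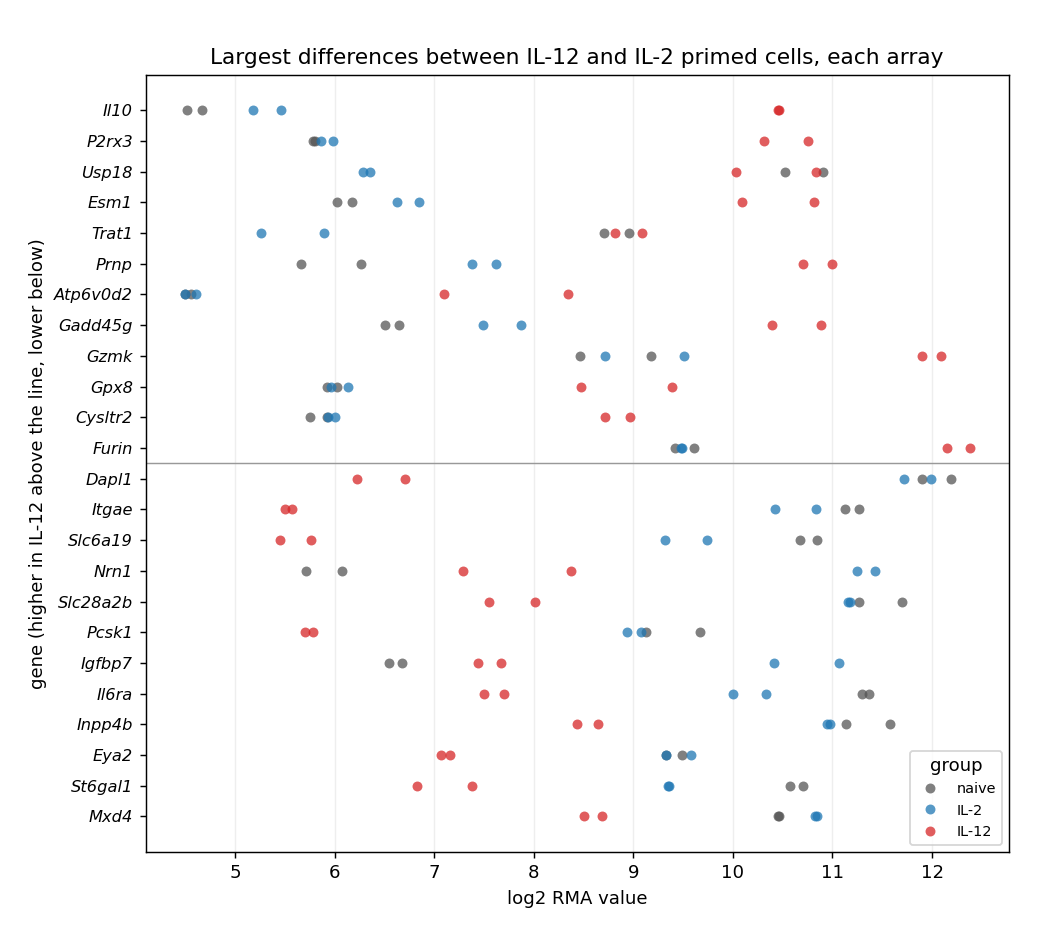
Log2 RMA value (horizontal axis) of the 12 largest rises and 12 largest falls between IL-12 and IL-2 primed cells, with each point 1 array and colours marking naive, IL-2 and IL-12 groups. Il10 lay near 10.46 in IL-12 and near 5.32 in IL-2 arrays, and Dapl1 near 6.47 and 11.85.

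Genes fixed for every comparison before the data were examined also moved. Il12rb2, the inducible chain of the IL-12 receptor, was 3.31-fold higher in IL-12 cells, Il2ra, the high-affinity IL-2 receptor chain, 2.59-fold higher, and Il18r1 2.12-fold higher. Tbx21, which encodes the transcription factor T-bet, was 2.23-fold higher, whereas Eomes, the related transcription factor, was 2.55-fold lower. Prf1, which encodes perforin, was 2.42-fold higher, and Klrg1, a marker of short-lived effector cells, was 3.84-fold higher. Ccr7, the lymph node homing receptor, was 2.77-fold lower, Cd27 1.98-fold lower and Il7r 1.84-fold lower. Limma adjusted p for these 10 genes lay between 6.17e-05 and 0.00107. Il12rb1 was 1.42-fold higher (limma adjusted p = 0.00766), a call lost without IL-2 replicate 1 (0.0724), IL-2 replicate 2 (0.0703) or IL-12 replicate 2 (0.066). Gzmb, which encodes granzyme B, had a log2 fold change of -0.17 ± 0.22 and Cd44 one of -0.03 ± 0.11, and neither passed the test (limma adjusted p = 0.643 and 0.899). Tcf7 was not analysed here.

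Of 19 tested genes responsive to IL-12 and STAT4, 16 rose and 1 fell in IL-12 against IL-2 cells (17 and 1 when adjusted over the list alone), with a median log2 fold change of 1.16. Besides Il10, Furin and Gadd45g, the transcription factor gene Irf8 rose by 2.43 ± 0.12. The shift was called by camera (adjusted p = 1.1e-11) and had an adjusted p of 0.123 with an estimated correlation. Of 22 naive and memory-associated genes, 14 fell and 2 rose (15 and 3 when adjusted over the list alone), including Actn1, which fell by 1.75 on the log2 scale, and Id3, a transcriptional inhibitor, which fell by 1.95. Camera called this fall (adjusted p = 2.73e-07; adjusted p = 0.293 with an estimated correlation). Of 18 terminal effector-associated genes, 9 rose and 4 fell, and the same numbers held when adjusted over the list alone. Zeb2 rose by 1.63 ± 0.13 and Prdm1, which encodes Blimp-1, by 1.33 ± 0.13, while Klrd1 fell by 1.42. That list lay just inside the threshold (camera adjusted p = 0.0494; adjusted p = 0.589 with an estimated correlation), and fry did not call it (adjusted p = 0.0705). It was outside it under 12 of 16 alternative settings, with adjusted p from 0.00444 to 0.377 over all of them. These included leaving out naive replicate 1 or 2 (0.102 each), IL-2 replicate 2 (0.118) or IL-12 replicate 2 (0.0569). Of 21 homing and adhesion receptors, 9 fell and 3 rose (11 and 4 when adjusted over the list alone; camera adjusted p = 0.0122; adjusted p = 0.293 with an estimated correlation). With Itgae and Ccr7, the chemokine receptor gene Ccr4 fell by 1.32 on the log2 scale, and Cxcr6 rose by 0.88 ± 0.10.

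Among 15 tested cytotoxic effector molecules, 5 rose and 1 fell, the same numbers when adjusted over the list alone, and the list was not called (camera adjusted p = 0.115). Fasl, which encodes Fas ligand, rose by 1.31 ± 0.18 and Serpinb9, a granzyme B inhibitor, by 1.16 ± 0.17. Among 12 effector cytokines and chemokines, 3 rose and 4 fell, the same when adjusted over the list alone. Csf1 rose by 2.15 ± 0.17 and Xcl1 fell by 1.19. That list had a median of -0.14 and a mean of 0.45, camera gave it the direction down and fry up, and neither called it (camera adjusted p = 0.768, fry adjusted p = 0.0705).

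Members of the glycolysis, cholesterol synthesis and DNA replication lists rose in IL-12 against IL-2 cells. Of 20 glycolysis genes, 11 rose and none fell (13 and none when adjusted over the list alone), led by Hk2, which encodes hexokinase 2, with a log2 fold change of 1.96 ± 0.12. Pfkl rose by 1.15 ± 0.18 and the glucose transporter gene Slc2a1 by 1.33 ± 0.22. Camera called the list (adjusted p = 9.13e-05; adjusted p = 0.589 with an estimated correlation), whereas fry did not (0.0873). Its mean log2 fold change of 0.66 was 0.38 without IL-12 replicate 1 (camera adjusted p = 0.01). The lactate transporter gene Slc16a3 read 11.26 and 9.61 on the 2 IL-12 arrays and Aldoc 10.38 and 8.19. Of 17 cholesterol synthesis genes, 10 rose and none fell (12 and none when adjusted over the list alone), among them Idi1 by 1.20 ± 0.20 (camera adjusted p = 8.75e-06; adjusted p = 0.589 with an estimated correlation; fry 0.116). Of 27 DNA replication and S phase genes, 13 rose and none fell (18 and none when adjusted over the list alone; camera adjusted p = 3.27e-07; adjusted p = 0.589 with an estimated correlation; fry 0.0705). Ccne1, which encodes cyclin E1, rose by 0.64 ± 0.11, a call lost without IL-2 replicate 2 (limma adjusted p = 0.0642). None of 29 mitosis genes passed the limma test, also when adjusted over the list alone, and camera gave an adjusted p of 0.606 and fry 0.642. Of 13 amino acid and integrated stress response genes, 8 rose and 1 fell (9 and 3 when adjusted over the list alone). The serine pathway gene Shmt2 rose by 0.96 ± 0.12 and the amino acid transporter gene Slc7a5 by 1.08 ± 0.15. Camera called that list (adjusted p = 0.0178; adjusted p = 0.589 with an estimated correlation; fry 0.0705), but not without IL-2 replicate 2 (0.0565) or IL-12 replicate 1 (0.0529).

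Markers of other cells differed between the primed groups too. Of 13 B cell markers, 10 rose and none fell in IL-12 against IL-2 cells, the same when adjusted over the list alone, with Ms4a1, which encodes CD20, at 8.38 against 6.27. Cd79a, a B cell receptor chain, rose by 1.62 ± 0.11 (list camera adjusted p = 1.05e-07; adjusted p = 0.127 with an estimated correlation). Of 6 MHC class II presentation genes, 5 rose, the same when adjusted over the list alone, including the invariant chain gene Cd74 by 2.04 ± 0.13 and H2-Aa by 2.25 ± 0.15. Camera called that list as well (adjusted p = 8.75e-05; adjusted p = 0.293 with an estimated correlation). Both lists were highest in naive cells, where Cd79a read 9.68 and 9.87 on the 2 arrays. Of 11 CD8 T cell identity genes, 5 fell and none rose, the same when adjusted over the list alone (camera adjusted p = 0.00124; adjusted p = 0.589 with an estimated correlation). Cd5 fell by 0.66 on the log2 scale. Of 6 tested myeloid and dendritic cell markers, 2 rose, Itgam and Mpeg1, while Lyz2, which encodes lysozyme, changed by 0.31 ± 0.15 (limma adjusted p = 0.182). The call of Mpeg1 was lost without IL-2 replicate 2 (limma adjusted p = 0.0703), IL-12 replicate 1 (0.076) or IL-12 replicate 2 (0.0934). The list was not called (camera adjusted p = 0.0961), and 2 members rose also when adjusted over the list alone.

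**Figure D2:**
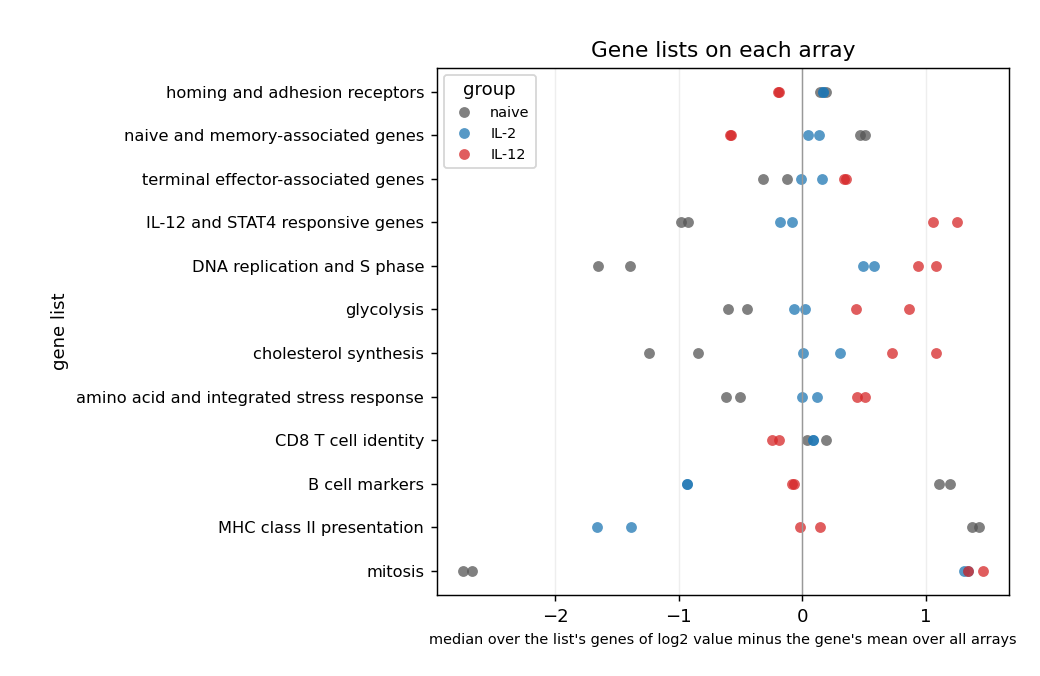
Median over each list's genes of the log2 value minus the gene's mean over all 6 arrays (horizontal axis), for the 11 lists that camera called between IL-12 and IL-2 cells and for mitosis, with each point 1 array. B cell and MHC class II lists ran from IL-2 (lowest) through IL-12 to naive, and on the mitosis list the closest IL-2 and IL-12 arrays both stood at 1.34.

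In total 2321 of 11147 genes passed limma's test at an adjusted p of 0.05 between IL-12 and IL-2 cells, 1095 higher and 1226 lower in IL-12 (1364 and 1132 with each array centred on its median), and 368 of them differed at least 2-fold. Without 1 array of either group the count fell to 954 (IL-2 replicate 1), 737 (IL-2 replicate 2), 1219 (IL-12 replicate 1) or 1031 (IL-12 replicate 2), and without either naive array it was 3533. With an estimated correlation none of the 29 tested lists was called by camera in this or the other comparisons. That setting did not call even the mitosis list against naive cells, where all 29 genes rose (camera adjusted p = 0.326 for IL-2 and 0.312 for IL-12). The absence of a call with it therefore cannot show that a list did not shift.

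In IL-2 primed cells compared with naive cells, Il2ra, Gzmb and the mitotic genes Kif11 and Bub1 were higher and the gut-homing receptor gene Ccr9 was lower. Ccr9 (probe set 10590620) showed the largest fall, from 12.45 in naive to 5.21 in IL-2 cells (log2 fold change -7.24 ± 0.13, n = 2 arrays per group; limma adjusted p = 2.17e-08). Nrn1 showed the largest measured rise at 43.6-fold, followed by the metallothionein gene Mt2 at 38.0-fold, Il2ra at 35.1-fold and Gzmb at 34.3-fold (limma adjusted p from 5.07e-08 to 1.59e-06). Ifitm1 was 31.6-fold higher, and the mitotic genes Kif11 and Bub1 were 29.1-fold and 27.7-fold higher. Hmmr was at least 26.3-fold higher, its naive mean of 4.96 being no higher than that of the Y-linked genes. After Ccr9, the falls were those of the Notch pathway gene Dtx1 (29.4-fold), the iron exporter gene Slc40a1 (21.6-fold), Usp18 (21.0-fold), Lyz2 (14.9-fold), Slc16a5, Rflnb and H2-Aa (13.3-fold).

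Ifng was 7.90-fold, Il12rb2 6.19-fold, Il18r1 2.30-fold, Il12rb1 1.93-fold, Tbx21 1.90-fold and Cd44 1.71-fold higher in IL-2 than in naive cells. Prf1 was 2.80-fold, Klrg1 1.90-fold and Eomes 1.81-fold lower. Il7r was 1.42-fold lower (limma adjusted p = 0.00642), a call lost without IL-2 replicate 1 (0.071). Ccr7 and Cd27 did not pass the test, with log2 fold changes of -0.19 ± 0.12 and 0.17 ± 0.10 (limma adjusted p = 0.216 and 0.196).

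All 29 mitosis genes and all 27 DNA replication genes rose in IL-2 against naive cells, also when adjusted over the list alone. Tpx2, a spindle assembly factor, rose by 4.40 ± 0.10 and the replication factor gene Gins1 by 3.38 ± 0.13. Camera called both lists (adjusted p = 1.86e-26 and 1.12e-16; adjusted p = 0.326 and 0.396 with an estimated correlation). Of 17 cholesterol synthesis genes 16 rose (17 when adjusted over the list alone) and of 27 oxidative phosphorylation genes 21 rose (22 when adjusted over the list alone). Sqle, which encodes squalene epoxidase, rose by 2.02 ± 0.23 and the succinate dehydrogenase gene Sdhd by 1.61 ± 0.15 (camera adjusted p = 3.44e-06 and 1.08e-05; adjusted p = 0.574 for both with an estimated correlation). Of 13 amino acid and integrated stress response genes 9 rose (11 when adjusted over the list alone), with the asparagine synthetase gene Asns up by 3.25 ± 0.24 (camera adjusted p = 0.000379; adjusted p = 0.447 with an estimated correlation). Of 20 glycolysis genes 11 rose and 1 fell (12 and 1 when adjusted over the list alone), among them Tpi1 by 1.90 ± 0.24 (camera adjusted p = 0.0435; adjusted p = 0.778 with an estimated correlation; fry 0.136). The glycolysis call was lost without naive replicate 1 (0.0967), naive replicate 2 (0.0682) or IL-2 replicate 1 (0.106), and under 3 settings that kept all arrays, up to 0.139. Of 19 genes responsive to IL-12 and STAT4, 9 rose and 2 fell, the same when adjusted over the list alone (camera adjusted p = 0.0329; adjusted p = 0.396 with an estimated correlation), a call lost without naive replicate 2 (0.0838) and with a filter at the 75th percentile (0.0831). Map3k8 rose by 1.53 ± 0.14.

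Members of the interferon-stimulated and naive-associated lists fell in IL-2 against naive cells. Of 25 interferon-stimulated genes 18 fell and 3 rose, the same when adjusted over the list alone, including Ifit3, which fell by 3.41 on the log2 scale, and Oas2, which fell by 2.98 (camera adjusted p = 1.08e-05; adjusted p = 0.396 with an estimated correlation). Of 22 naive and memory-associated genes 14 fell and 3 rose, the same when adjusted over the list alone. Cxcr5 fell by 2.23 and Lef1, a transcription factor of naive T cells, by 0.77 (camera adjusted p = 0.001; adjusted p = 0.396 with an estimated correlation). Markers of other cells moved with these falls: all 13 B cell markers, 5 of 6 MHC class II genes and 5 of 6 myeloid and dendritic markers fell, also when adjusted over the list alone. Cd79a fell by 2.74, Cd74 by 3.20 and Csf1r, a macrophage receptor gene, by 2.86 on the log2 scale. Camera called these lists (adjusted p = 2.1e-11, 6.25e-05 and 0.000348; adjusted p = 0.146, 0.326 and 0.396 with an estimated correlation). Naive cells were sorted, and the labels name no sort of the primed cells.

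In all, 5095 of 11147 genes passed limma's test between IL-2 and naive cells, 2873 higher and 2222 lower in IL-2, with 1202 changed at least 2-fold. The count was 3341 without IL-2 replicate 1, and with each array centred on its median 2439 genes were higher and 3006 lower.

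In IL-12 primed cells compared with naive cells, Il2ra (probe set 10469278) showed the largest measured rise, from 6.49 to 12.99 (log2 fold change 6.51 ± 0.11, n = 2 arrays per group; limma adjusted p = 1.21e-08). Mt2 was 76.4-fold, the mitochondrial carbonic anhydrase gene Car5b 60.3-fold and Ifitm1 51.6-fold higher. Il10 was at least 58.2-fold higher, since its naive mean of 4.59 lay within the 3.32 to 4.96 of the Y-linked genes. The fatty acid desaturase gene Fads2, Ifng and Bhlhe40 were 44.1-fold, 40.9-fold and 31.2-fold higher. Ccr9 fell the most, to 5.30 from 12.45, and Itgae, Dapl1, Slc6a19 and Dtx1 were 50.4-fold, 47.6-fold, 35.6-fold and 29.1-fold lower. Slc16a5, Slfn5 and Ifngr2, a chain of the interferon gamma receptor, were 19.6-fold, 19.3-fold and 18.9-fold lower. Limma adjusted p for these 16 genes lay between 1.21e-08 and 5.63e-07.

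Gzmb was 30.6-fold and Il12rb2 20.5-fold higher in IL-12 than in naive cells, Il18r1 4.89-fold, Tbx21 4.22-fold, Il12rb1 2.75-fold, Klrg1 2.02-fold and Cd44 1.68-fold. Eomes was 4.62-fold, Ccr7 3.16-fold, Il7r 2.61-fold and Cd27 1.76-fold lower. Prf1 did not pass the test, with a log2 fold change of -0.21 ± 0.14 (limma adjusted p = 0.232).

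All 29 mitosis genes, all 27 DNA replication genes and all 17 cholesterol synthesis genes rose in IL-12 against naive cells, also when adjusted over the list alone. Birc5, which encodes survivin, rose by 4.29 ± 0.10, Uhrf1 by 3.64 ± 0.15 and Idi1 by 3.03 ± 0.20 (camera adjusted p = 1.21e-20, 8.49e-15 and 4.18e-07; adjusted p = 0.312, 0.456 and 0.528 with an estimated correlation). Of 27 oxidative phosphorylation genes 26 rose, the same when adjusted over the list alone, among them Cox5a by 1.52 ± 0.11 (camera adjusted p = 5.92e-06; adjusted p = 0.528 with an estimated correlation). Of 20 glycolysis genes 16 rose and 2 fell, the same when adjusted over the list alone, with Hk2 up by 2.66 ± 0.12 (camera adjusted p = 0.000638; adjusted p = 0.588 with an estimated correlation). Of 13 amino acid and integrated stress response genes 11 rose, also when adjusted over the list alone, with Asns up by 4.21 ± 0.24 (camera adjusted p = 0.000263; adjusted p = 0.456 with an estimated correlation).

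Of 19 genes responsive to IL-12 and STAT4, 14 rose and 2 fell in IL-12 against naive cells, the same when adjusted over the list alone, Il12rb2 by 4.36 ± 0.13 (camera adjusted p = 5.92e-06; adjusted p = 0.195 with an estimated correlation). Of 15 cytotoxic effector molecules 9 rose and 1 fell, the same when adjusted over the list alone, with Fasl up by 2.50 ± 0.18 and Gzmk by 3.17 ± 0.28 (camera adjusted p = 0.0301; adjusted p = 0.528 with an estimated correlation). That call was lost without naive replicate 1 (0.0843), with a filter at the 75th percentile (0.0526) and with quantile normalization (0.0936). Of 18 terminal effector-associated genes 10 rose and 2 fell (10 and 3 when adjusted over the list alone), including Prdm1 by 2.18 ± 0.13 (camera adjusted p = 0.0488; adjusted p = 0.617 with an estimated correlation), a call lost without naive replicate 2 (0.168) and under 3 settings that kept all arrays. Of 22 naive and memory-associated genes 19 fell and 1 rose, the same when adjusted over the list alone. Il6ra fell by 3.73 and Actn1 by 2.46 on the log2 scale (camera adjusted p = 1.88e-07; adjusted p = 0.312 with an estimated correlation). Of 25 interferon-stimulated genes 15 fell and 5 rose, the same when adjusted over the list alone. Ifit1 fell by 3.81 on the log2 scale, whereas Gbp3, a guanylate-binding protein gene, rose by 2.27 ± 0.10 (camera adjusted p = 0.00072; adjusted p = 0.456 with an estimated correlation). Of 11 CD8 T cell identity genes 7 fell and none rose, the same when adjusted over the list alone, and Cd8b1 fell by 0.63 (camera adjusted p = 0.0158; adjusted p = 0.528 with an estimated correlation). All 13 B cell markers, 5 of 6 MHC class II genes and 5 of 6 myeloid and dendritic markers fell here too, also when adjusted over the list alone, and 1 myeloid and dendritic marker rose. Ebf1, a B cell transcription factor gene, fell by 1.71, H2-Aa by 1.48 and Lyz2 by 3.59 (camera adjusted p = 2.99e-06, 0.00426 and 0.00677; adjusted p = 0.195, 0.424 and 0.456 with an estimated correlation).

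In all, 6454 of 11147 genes passed limma's test between IL-12 and naive cells, 3482 higher and 2972 lower in IL-12, with 1922 changed at least 2-fold (3134 higher and 3415 lower with each array centred on its median). Naive replicate 1 read higher than the other arrays on 6617 unnamed probe sets with the lowest identifiers, with a median of 7.10 against 6.28 to 6.61.

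Il2ra, Mt2, Ifitm1 and Gzmb rose and Ccr9, Dtx1 and Slc16a5 fell in both primed groups against naive cells. In all, 2436 genes were higher and 1873 lower in both, where independent lists of those lengths would share 897 and 592. Unchanged groups simulated against the same naive arrays shared 0.1 genes on average over 20 simulations. Those simulations held no changed genes, so few calls were possible. Their count cannot show how much of the overlap comes from the shared naive arrays. Across genes, which are not independent replicates, the fold changes correlated at 0.885 (0.503 in the simulations), with a covariance of 0.627 against 0.0085. With a separate naive array for each primed group, a setting chosen after seeing the data, 4188 or 3792 genes were called in the same direction, depending on which array served which group, and the covariance was 0.619 or 0.603. Of the 4309 genes changed in the same direction, 1038 also differed between IL-12 and IL-2 cells, and 67 genes changed in opposite directions.

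**Figure D3:**
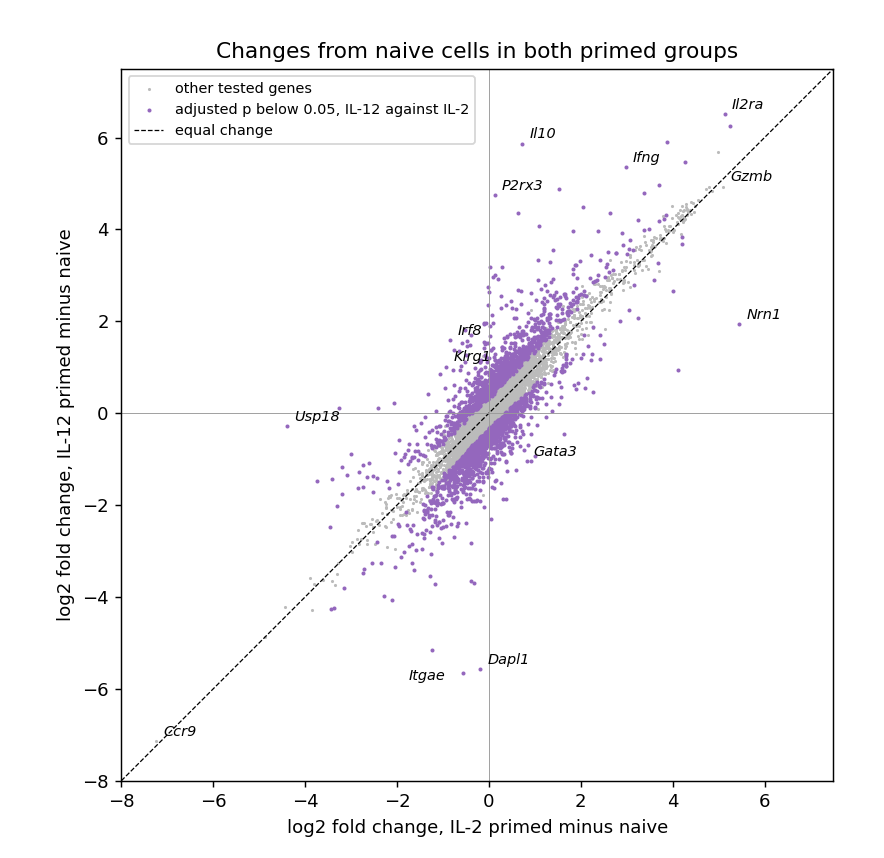
Log2 fold change from naive cells in IL-2 primed (horizontal axis) and IL-12 primed cells (vertical axis), 1 point per tested gene, with genes that differed between IL-12 and IL-2 in purple and a dashed line of equal change. Il10 and P2rx3 rose against naive mainly in IL-12 cells, Dapl1 and Itgae lay far below the line, and Ccr9 and Gzmb lay near it.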

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

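For this part, the tests of the myeloid markers, of the type I interferon-stimulated genes and of the glycolysis list without 1 array were chosen only after the result was seen, as were the margins each test needed to exclude an explanation; the other tests were written before the values they use were looked at.

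These genes, from the fixed lists and the named genes, were drawn out because they moved in opposite directions against naive cells in the IL-2 and IL-12 groups, which limma called in both comparisons. The direct comparison is the difference of those changes, and all 67 genes that moved in opposite directions passed it, so its adjusted p (8.79e-06 to 0.000536 here) is no independent evidence. Irf8, Gbp5, Klrg1 and Zeb2 fell against naive in IL-2 and rose in IL-12 cells, with log2 differences between IL-12 and IL-2 of 2.43, 1.99, 1.94 and 1.63. Mxd4, Id3, Gata3, Klrd1, Nr4a3, Cd160 and Ifnar2 rose in IL-2 and fell in IL-12 cells, with differences of -2.24, -1.95, -1.86, -1.42, -1.22, -1.19 and -1.10.

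B cell and MHC class II genes were higher in IL-12 than in IL-2 cultures and highest in naive cells. More of every kind of non-T cell in the IL-12 cultures stays open. The 6 myeloid and dendritic markers had a median log2 change of 0.23 against 0.88 for the B cell markers. Only 2 of them lay above the filter value of 6.83 in a primed group, Cd68 with a change of -0.03 and Itgam with 0.95. Mpeg1, which also rose, had means of 5.62 in IL-2 and 6.59 in IL-12 cells. Itgam, unlike the B cell markers, was lower in naive (6.31) than in IL-2 cells (6.57). Carried-over B cells may be the source, and this stays open: 36.4% of 22 further B lineage genes passed the test as higher in IL-12, between the bounds set beforehand, and 3 were lower. Not all of these genes followed the B cell markers. Cd24a, among the higher, and Napsa, among the lower, had larger means in IL-2 (10.14 and 9.03) than in naive cells (8.72 and 7.98). Cd79a and Ms4a1 read 9.77 and 9.27 in naive, 7.03 and 6.27 in IL-2 and 8.65 and 8.38 in IL-12 cells. Cr2 and Fcer2a, also measured in naive cells, changed by 0.22 and -0.06 between IL-12 and IL-2 without passing the test. Both lay below 6.83 on every primed array (5.30 to 5.72 for Cr2, 5.66 to 5.99 for Fcer2a), so these 2 genes cannot decide the question. Expression by the T cells under IL-12 was not tested.

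Usp18 was 17.3-fold higher in IL-12 than in IL-2 cells and fell against naive in IL-2 cells. The IL-12 arrays (10.84 and 10.03) read near the naive arrays (10.53 and 10.90). The difference thus came with a fall in IL-2 cells and no rise above naive in IL-12 cells. A type I interferon response that raised such genes together in the IL-12 cultures at the time of sampling is argued against by 17 other such genes. Their median log2 change was -0.234 with an SD of 0.488, and -0.27 over the 14 of them above the filter value in a primed group. All 17 were on the fixed interferon-stimulated list, whose values had been seen, so the outcome was largely known beforehand. They cannot speak to a response that had already ended in these genes. A response to interferon gamma stays open: 11.1% of 9 interferon gamma selective genes passed the test as higher in IL-12, under the bound of 25% set beforehand, but the exact 95% binomial interval reached 48.2%. Of those 9 genes 2 were lower, while Gbp3 and Gbp5, not among them, rose by 1.69 and 1.99 and Ifng rose by 2.37. Cross-hybridisation of its 1 probe set and an effect of IL-12 on this gene alone were not tested.

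Glycolysis genes were higher in IL-12 than in IL-2 cultures, more so on IL-12 replicate 1. Something particular to that 1 array could account for part: without it the list's mean log2 change was 0.384 against 0.658. That mean lay above the 0.329 set as the bound by less than its standard error over genes of 0.144, which leaves the explanation open. No label says that the IL-12 arrays came from separate cultures, so the state of a culture and a technical difference cannot be told apart. Low oxygen in the IL-12 cultures also stays open, as 40% of 15 low oxygen response genes passed the test as higher in IL-12, with a median log2 change of 0.59 and none lower. A direct effect of IL-12 priming was not tested apart from these.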

How the results depend on the processing

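The comparison with a separate naive array for each primed group (4188 and 3792 shared genes, against 4309) was chosen after the result was seen; the other alternatives were planned. A gene that the filter of an alternative left out had no result under it and was not counted as lost. The next counts are for the alternatives that kept all arrays, other than the test against a 1.5-fold change. Wherever they were tested, 101 of 104 named genes called between IL-12 and IL-2 stayed called in the same direction. So did 112 of 116 between IL-2 and naive and 109 of 112 between IL-12 and naive. Without any single array 81, 104 and 107 did, the lone array of a group being assumed to vary like the others.

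For IL-12 against IL-2, array weights gave 3839 genes, the compared arrays alone 3533, and the test against 1.5-fold 256; leaving out 1 array gave 737 to 3533. The test against 1.5-fold gave 1152 for IL-2 and 2070 for IL-12 against naive and 1007 shared genes, a stricter question by construction; leaving out 1 array gave 3341 to 5786 for IL-2, 5081 to 6844 for IL-12 and 2938 to 4966 shared genes. For IL-12 against IL-2, leaving out either naive array is the same fit as the compared arrays alone, since a lone array adds nothing to the estimated spread. The 2 naive arrays differed more (SD of log2 differences 0.254) than the IL-2 (0.164) or IL-12 arrays (0.187), and their spread enters the fit on all arrays. Dropping an array of a compared group lowers the degrees of freedom. Otherwise the cause was not tested. With an estimated correlation camera called 0, 0 and 0 lists, and fry called 9, 22 and 23, of which camera also called 6, 11 and 15. With a replicate block, 2414, 5128 and 6471 genes, 11, 12 and 15 lists and 4357 shared genes were found; deviations of equally numbered arrays correlated across genes at 0.0152, -0.0223 and 0.153 (the last IL-2 with IL-12), and the labels state no pairs, so none were assumed, although Fosb, Dusp1 and Jun read higher on replicate 1 of each group.

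Directions turned for Cd44, Gp9, Slc4a1, Foxp3 and Fos, none of them called in those comparisons. With quantile normalization log2 changes were 0.028 for Cd44 and 0.0064 for Gp9 (IL-12 against IL-2), 0.055 for Slc4a1 (IL-2 against naive), and 0.097 for Foxp3 and 0.097 for Slc4a1 (IL-12 against naive). With centred arrays they were 0.018 for Gp9 (IL-12 against IL-2) and -0.073 for Foxp3 (IL-2 against naive). Leaving out 1 array gave, for IL-12 against IL-2, -0.12 to 0.070 for Cd44, -0.092 to 1.94 for Fos, -0.16 to 0.069 for Foxp3, -0.065 to 0.089 for Slc4a1 and -0.078 to 0.062 for Gp9. It gave -0.20 to 0.26 for Foxp3 and -0.072 to 0.0044 for Slc4a1 in IL-2 against naive, and -0.25 to 0.21 for Foxp3 and -0.10 to 0.055 for Slc4a1 in IL-12 against naive. The cause was not tested. On arrays, signal near background limits folds of genes low in 1 group; the filter asks for 2 of 6 arrays above 6.83 and keeps such genes.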

Other observations

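The array differences in immediate early genes and the sign comparison of list measures were looked at only after the result was seen; the list tests were fixed in advance.

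Some inhibitory and costimulatory receptors changed against naive cells, while camera called neither list in either primed group. Fry, which asks whether a list's genes move one way on balance, called both as higher in IL-2 and IL-12 cells (adjusted p = 0.00284 and 0.00392 for inhibitory, 0.0107 and 0.0173 for costimulatory receptors). Fry does not set a list against the other genes, and against naive it called 22 and 23 of 29 lists. In IL-12 cells the inhibitory list had a median log2 change of -0.08 and a mean of 0.55, so its genes did not rise as a whole. Against naive cells, 9 of 17 inhibitory receptors and exhaustion-associated genes rose and 5 fell in IL-2 cells and 8 rose and 6 fell in IL-12 cells (9 and 5, and 8 and 7, when adjusted over the list alone; camera adjusted p = 0.119 and 0.562). Ctla4 rose by 4.20 ± 0.11 and 3.68 ± 0.11 and Pdcd1, which encodes PD-1, by 2.43 ± 0.16 and 2.50 ± 0.16. Between IL-12 and IL-2 cells 3 rose and 5 fell (3 and 6 when adjusted over the list alone; camera adjusted p = 0.229), and Tox, a transcription factor gene, fell by 1.92. Of 15 costimulatory and activation receptors 5 rose and 6 fell in IL-12 against IL-2 cells, the same when adjusted over the list alone, with Slamf1 up by 1.06 ± 0.10 and Tnfsf8 down by 1.80 (camera adjusted p = 0.662). Against naive 5 rose and none fell in IL-2 cells and 6 rose and 6 fell in IL-12 cells, the same when adjusted over the list alone (camera adjusted p = 0.0716 and 0.763). Of 32 transcription regulators 9 rose and 10 fell in IL-12 against IL-2 cells (10 and 11 when adjusted over the list alone; camera adjusted p = 0.726, and 0.679 and 0.763 against naive for IL-2 and IL-12), and Irf4 rose against naive by 1.83 ± 0.11 in IL-2 and 2.47 ± 0.11 in IL-12 cells.

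Among 22 cytokine receptors 6 rose and 9 fell in IL-12 against IL-2 cells (7 and 10 when adjusted over the list alone; camera adjusted p = 0.352), with Il6st, the shared gp130 chain, up by 1.16 ± 0.10; against naive camera gave 0.679 for IL-2 and 0.168 for IL-12. Of 20 genes responsive to IL-2 and STAT5, 6 rose and 5 fell (7 and 5 when adjusted over the list alone; camera adjusted p = 0.662, and 0.466 and 0.477 against naive), with Pim2 up by 1.26 ± 0.12 and Cish down by 1.03. Of 5 genes of the type 2 cytokine programme Gata3 and Ccr4 fell in IL-12 against IL-2 cells (1 higher and 2 lower when adjusted over the list alone; camera adjusted p = 0.298, and 0.381 and 0.763 against naive). Of 12 pro-apoptotic genes 3 rose and 1 fell, the same when adjusted over the list alone, with Pmaip1 up by 1.04 ± 0.12 (camera adjusted p = 0.255, and 0.633 and 0.886 against naive). Of 7 anti-apoptotic genes 2 fell (3 when adjusted over the list alone; camera adjusted p = 0.115, and 0.373 and 0.0932 against naive); Bcl2 fell by 0.96, a call lost without IL-2 replicate 2 (limma adjusted p = 0.0509). Of 7 natural killer receptors 1 rose and 2 fell (2 and 3 when adjusted over the list alone; camera adjusted p = 0.385, and 0.644 and 0.553 against naive), with Klrb1f up by 1.01 ± 0.15. None of 3 CD4 and regulatory T cell markers passed between IL-12 and IL-2 cells, also when adjusted over the list alone (camera adjusted p = 0.31, and 0.373 and 0.763 against naive), and none of 3 erythroid and platelet markers passed in any comparison (camera adjusted p = 0.768, 0.519 and 0.522).

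Camera and fry both called 6 lists between IL-12 and IL-2, 11 in IL-2 against naive and 15 in IL-12 against naive. Fry alone called 3, 11 and 8. Between IL-12 and IL-2 these were lower cytokine receptors (0.0326), type 2 genes (0.00588) and anti-apoptotic genes (0.0106). In both primed groups against naive they were effector cytokines, homing receptors, inhibitory and costimulatory receptors, genes responsive to IL-2 and STAT5, anti-apoptotic genes and CD4 and regulatory T cell markers. Fry alone also called cytotoxic molecules, type 2 genes, cytokine receptors and terminal effector-associated genes in IL-2 cells and transcription regulators in IL-12 cells. The remaining camera results against naive were these. For homing receptors camera gave 0.684 for IL-2 and 0.168 for IL-12 cells, for terminal effector-associated genes 0.31 in IL-2, for cytotoxic molecules 0.124 in IL-2, for effector cytokines 0.161 and 0.562, and for CD8 T cell identity 0.684 in IL-2. Between IL-12 and IL-2 cells camera gave 0.662 for interferon-stimulated genes (5 of 25 rose and 6 fell, the same when adjusted over the list alone) and 0.0961 for oxidative phosphorylation (2 of 27 rose, 1 when adjusted over the list alone). The sign of the median, the mean or a test differed for 13 list results, none of which camera called. Between IL-12 and IL-2 cells these were effector cytokines, transcription regulators, immediate early genes and interferon-stimulated genes (median -0.07, mean 0.11). In IL-2 against naive they were cytokine receptors, transcription regulators, CD8 T cell identity and natural killer receptors (median 0.37, mean -0.06). In IL-12 against naive they were the type 2 programme, cytokine receptors, transcription regulators, CD4 and regulatory T cell markers, and inhibitory receptors (median -0.08, mean 0.55). Among the genes that check the animals' sex, Xist had means of 12.25, 12.17 and 11.74 in naive, IL-2 and IL-12 cells, and the Y-linked genes Eif2s3y, Kdm5d and Uty had group means between 3.32 and 4.96.

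Immediate early genes differed between arrays of one group, a pattern noticed in the values. Fosb read 9.35 and 7.82 on the IL-2 arrays, 9.91 and 8.32 on the IL-12 arrays and 8.03 and 7.63 on the naive arrays. Dusp1 read 11.75 and 10.34, 11.43 and 10.36, and 10.02 and 9.81. Of 13 immediate early and handling stress genes 1 fell in IL-12 against IL-2 cells, also when adjusted over the list alone (camera adjusted p = 0.935, and 0.87 and 0.763 against naive for IL-2 and IL-12).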
